A study of Caenorhabditis elegans with 2 samples.

How the data were processed

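The samples were whole L4 larvae of *Caenorhabditis elegans*, 48 h old, grown from larvae synchronised by starvation at the L1 stage. The animals were of both sexes, and the strain carried a transgene that expresses NHR-111 with a C-terminal tag containing GFP, together with an unc-119 rescue. Per the labels, chromatin was fragmented by sonication and precipitated with an antibody against GFP, and the 2 libraries were separate biological replicates of a single group. Samples were assigned to the group and given replicate numbers from the labels.

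The authors deposited interval lists in assembly ce11, per the labels. According to text files deposited with the samples, each replicate's list was made from its own alignment and a control alignment shared by both replicates, and the pooled list from both alignments and the same control. The thresholded list was derived from these 3 lists by the irreproducible discovery rate, a measure of how well ranks agree between replicates. The aligner, the peak caller, its settings and the threshold are not given in the sources used here. The control alignment was not analysed here. Each full list has 30000 intervals, which includes background by the authors' design.

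For each interval the authors deposited a signal value, whose scale is not given in the sources used here, so ratios, SDs and Pearson's r of it hold only on the scale as deposited. It was used to rank, filter and describe intervals within a list, and to compare the replicates at matched peaks, on the log2 scale for Pearson's r and as deposited for means, SDs and ratios. No scaling between the replicate lists was applied. The deposited −log10 q-value was not used for ranking, because in the thresholded list it did not rise steadily with the signal (rank correlation 0.175). Summit positions came from the point-source offset deposited for each interval. No read totals were in the files used, so depth is unknown, and exact binomial intervals (95%, Clopper-Pearson) cover only the counting error of peaks or genes.

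Interval ends were checked against the reference chromosomes of assembly WBcel235, the same sequence as ce11, and all lay within them. Genes, biotypes and transcript parts came from the Ensembl annotation of that assembly, with 46890 genes on the 6 nuclear chromosomes, of which 19973 are protein-coding. Symbols came from the RefSeq annotation by WormBase identifier and were found for 46881 genes. Coordinates are given from 1.

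Replicates were compared over the 501 strongest intervals of each, the length of the thresholded list, and summits within 200 bp were counted as shared. Chance was estimated from 1000 circular shifts of the summits within each chromosome. Thresholded peaks were matched to the nearest summit within 200 bp in each replicate, and correlations were tested with 100000 permutations. Means ± SD of signal are over the 2 replicates.

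A gene was counted as bound if a thresholded summit lay from 1000 bp upstream to 200 bp downstream of its start. Shares of summits in annotation classes were tested against the circular shifts. The classes were ordered as promoter window, 5' UTR, coding exon, 3' UTR, intron and intergenic sequence, and the first that applied was used. Biotypes with at least 10 genes and gene lists with at least 5 genes were tested with two-sided Fisher's exact tests against all other genes (for lists, all other protein-coding genes), with Benjamini-Hochberg adjustment over biotypes or lists and a threshold of 0.05. The 32 lists held transcription factor families, housekeeping groups, tissue markers and signalling genes, and were fixed before the data were examined. Chromosome shares were tested with exact binomial tests against length.

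Words of 6 bases were compared between the 101 bp around each summit and a window of the same length centred 300 bp away on a randomly drawn side, by an exact sign test over the peaks in which only one of the windows held the word. Intervals around the native nhr-111 and unc-119 genes were listed to 20 kb on either side.

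The genes named were fixed by rule before the data were examined. They were nhr-111 and unc-119, and the genes with the start nearest to the 15 strongest thresholded peaks. They also included up to 4 bound members of highest signal in each list past the threshold and in the nuclear hormone receptor list, and up to 5 genes nearest to strong intervals of a single replicate, defined as intervals among the 501 strongest with no summit within 200 bp among the 5010 strongest of the other. Neighbouring genes, host genes, bound members of lists that did not pass and the genes named in the closing observations were chosen after their values were seen.

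The alternatives fixed in advance were the 250 strongest thresholded peaks, each replicate alone, overlapping peaks merged (496 regions), summits within 50 bp or overlaps of at least 1 bp, the 1002 strongest intervals of each replicate, windows of 500 bp upstream to 100 bp downstream and 2000 bp upstream to 500 bp downstream, assignment to the nearest start, 10000 rotations of bound labels along gene order, expected shares by protein-coding genes, word windows of 100 bp on either side and flanks 600 bp away. Added after the data were seen were analyses without peaks within 250 bp of a tRNA gene start, and without peaks within 250 bp of the start of any tRNA, snoRNA, snRNA, rRNA, miRNA or ncRNA gene.

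The statistics were tested on simulated data. With 200 of 501 intervals planted as shared, 202 were found, and with none planted 1 was found. The list of 78 ribosomal protein genes, planted as bound 10 times as often as other genes among 19973, was found in 90 of 100 simulations. Other lists were called 4 times over these 100 simulations. No smaller list was planted, so the chance of finding one is not known. A word planted in 15% of 501 summit windows was found, and no word was called without planting. These windows lay at random positions, so the simulation did not carry the difference in GC content between the real summits and flanks. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. There were no groups to compare, so no paired analysis, no test between groups and no test for outlying samples was run.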

Results

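Chromatin immunoprecipitation and sequencing was carried out on whole *Caenorhabditis elegans* at the L4 larval stage, 48 h old, from a strain that carried a transgene encoding NHR-111 fused to GFP. NHR-111 belongs to the nuclear hormone receptor family of transcription factors, and chromatin bearing the fusion was recovered with an antibody against GFP. The series held a single group of 2 biological replicates, so no condition was compared with another. The comparisons that the design allowed were replicate against replicate, and peak positions against the genome and its annotation. The authors deposited 30000 intervals for each replicate, 30000 for both replicates pooled, and a list of 501 peaks thresholded by the irreproducible discovery rate. These 501 thresholded peaks were the 501 intervals of highest signal in the pooled list. Of them, 237 were among the 501 strongest intervals of both replicates, and 495 had a summit within 200 bp in both full replicate lists. The largest width in the list was shared by 481 (96.0%). The signal value deposited for each interval ran from 101.5 to 432 among the thresholded peaks. The files used held no read totals, so the depth of each replicate is unknown. All positions are in assembly ce11.

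The first question was how far the replicates recovered the same sites. Both replicates placed the snoRNA gene ZK994.7, the ribosomal protein gene rpl-3 and the snoRNA gene C51F7.4 among their 6 strongest intervals. Of the 501 highest-signal intervals of replicate 1, 249 (49.7%, exact 95% interval 45.2 to 54.2%) had a summit within 200 bp of one of the 501 highest-signal intervals of replicate 2. Circular shifts of the replicate 2 summits along their chromosomes gave a mean of 0.194% and at most 1.40% (permutation p = 0.001, one-sided, the smallest that 1000 shifts can give). The share was 62% among the top 50 intervals of each replicate, 61.0% among the top 100 and 30.7% among the top 5000, where shifts gave 2.01%. Both replicate lists were called against the same control alignment, and the shifts do not remove what the lists share through it.

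Across the 495 thresholded peaks with a matching interval in both replicates, signal correlated weakly between the replicates, with Spearman's rho of 0.28 and Pearson's r of 0.40 on the log2 scale (permutation p = 1e-05 for both, the smallest that 100000 resamples can give). Peaks are not independent replicates, and these had been selected on their pooled signal. Among the 501 intervals selected on replicate 1 alone, the 462 with a match in replicate 2 had a rho of 0.60. Among the 501 selected on replicate 2 alone, the 464 with a match in replicate 1 had a rho of 0.53. Strong intervals without a match were left out of both values. The median distance between the replicate summits of a peak was 25 bp, and the median SD of signal between replicates was 18.4% of the mean. This SD includes a difference in scale between the lists, since the median ratio of replicate 2 to replicate 1 signal was 1.18, and the scale of the signal is not given in the sources used here.

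**Figure D1:**
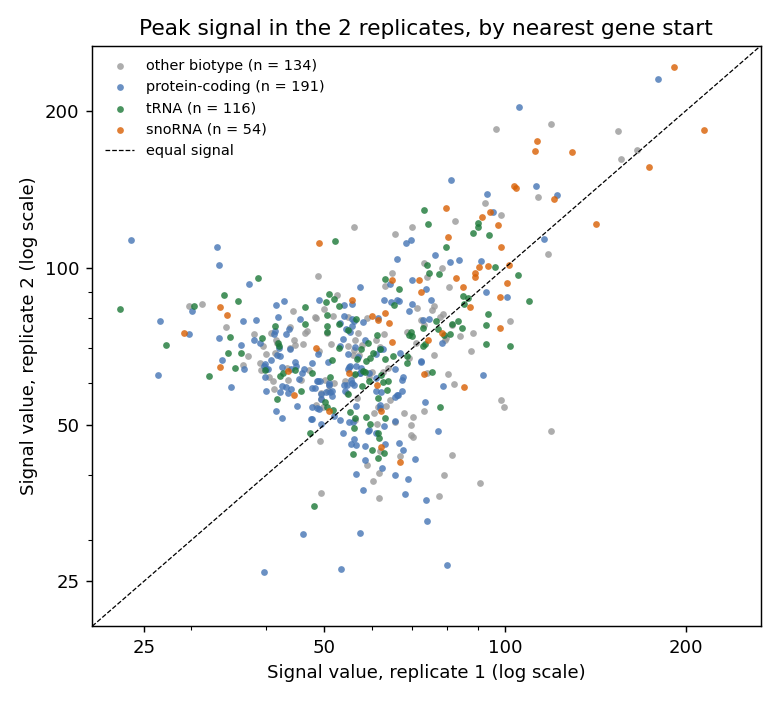
Signal value of each thresholded peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, coloured by the biotype of the nearest gene start; the dashed line marks equal signal. The 495 points scatter widely around the line (rho 0.28), and the peaks nearest to snoRNA genes reach the highest signals.

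Some intervals were strong in a single replicate. In replicate 1, 108 of the 501 strongest intervals (21.6%) had no summit within 200 bp among the 5010 strongest of replicate 2, and in replicate 2 there were 109 (21.8%). The strongest of these lay 293 bp upstream of cox-5A, which encodes a cytochrome c oxidase subunit. Its signal was 113 at rank 42 in replicate 2 and 23.8 at rank 14463 in replicate 1, and it is among the 501 thresholded peaks, at pooled rank 183. An interval in the promoter window of vha-2, a proteolipid subunit gene of the vacuolar ATPase, had its summit 18 bp upstream of the start and ranked 51 in replicate 1, with no match among the 30000 intervals of replicate 2. The others named by the same rule were nearest to T26A8.4, F56D12.10 and C18A11.13, with signals of 98.8, 85.6 and 85.2 in replicate 2. In replicate 1 the interval at C18A11.13 had a match at rank 5556 with a signal of 31.2, and those at T26A8.4 and F56D12.10 had none.

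The 15 strongest thresholded peaks lay mostly at genes for small RNAs. The nearest start belonged to a snoRNA gene in 8 of them, to another non-coding RNA gene in 5 and to a protein-coding gene in 2. The strongest peak, at chromosome V 8500427 to 8500661 in an intron of pxn-1, had its summit 14 bp upstream of ZK994.7, a snoRNA gene. Its signal was 191 in replicate 1 and 242 in replicate 2 (mean 217 ± 36.0, SD, n = 2). The second, at chromosome III 3867491 to 3867689, had its summit 260 bp upstream of rpl-3, a large ribosomal subunit protein gene, with a mean replicate signal of 205 ± 35.6 (SD, n = 2). The third lay in an intron of frm-7, with its summit 37 bp inside the snoRNA gene C51F7.4 and a mean of 199 ± 21.4 (SD, n = 2). The other snoRNA genes in this set were W03C9.9, T03F7.8, T19B4.8, Y75B12B.12, T02E1.9 and F30H5.4, with summits from 2 to 80 bp upstream of the annotated starts. The peak at rpr-1, the RNA component of RNase P, had its summit 25 bp inside the gene at chromosome I 13463980, in an intron of the Integrator subunit gene ints-8. Its replicate signals were close together, with a mean of 159 ± 4.11 (SD, n = 2).

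The remaining non-coding genes of the 15 were K02F3.13, R12E2.18, R10E11.10 and Y65B4BR.10. R12E2.18 overlaps the snRNA gene sls-2.4 (chromosome I 4172206 to 4172315), one of the SL2 RNA genes described in the closing observations. The peak assigned to K02F3.13 lay 1095 bp from it, in a coding exon of dos-3. That assigned to R10E11.10 also lay near cbp-1, a histone acetyltransferase gene, at −890 bp from its start, and that at Y65B4BR.10 lay 266 bp upstream of wwp-1, a ubiquitin ligase gene. The other protein-coding gene was mdt-26, a Mediator subunit gene, whose peak lay 618 bp downstream of the start in an intron. Its signals of 106 in replicate 1 and 203 in replicate 2 differed more than those of the other 14.

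Genes for tRNAs and snoRNAs carried the peaks far more often than other genes. A summit lay from 1000 bp upstream to 200 bp downstream of the start in 177 of 612 tRNA genes (28.9%, exact 95% interval 25.4 to 32.7%), against 1.23% of all other genes (odds ratio 32.7, adjusted p = 9.5e-172, two-sided Fisher's exact test, Benjamini-Hochberg over 11 biotypes). Among snoRNA genes the count was 62 of 346 (17.9%, odds ratio 14.7, adjusted exact p = 3.3e-45). Among snRNA genes it was 11 (8.53%, odds ratio 5.85, adjusted exact p = 1.2e-05), and among genes annotated as ncRNA 226 of 7764 (2.91%, odds ratio 2.23, adjusted p = 1.7e-20). Protein-coding genes were lower than the rest, at 209 of 19973 (1.05%, odds ratio 0.520, adjusted exact p = 3.8e-16). Genes for piRNAs, at 0.280%, and pseudogenes, at 0.376%, were lower as well (adjusted exact p = 3.2e-72 and 2.0e-07). Counted by summits in these windows, the differences from circular shifts did not pass the test, at 3.59% against 4.40% for piRNA genes and 1.60% against 2.17% for pseudogenes (permutation p = 0.41 and 0.51). By nearest start both were lower than after shifts, with 14 peaks against a mean of 29.9 for piRNA genes and 7 against 27.3 for pseudogenes (permutation p = 0.002 for each, the smallest possible). Windows of ncRNA genes held 35.7% of summits against 7.90% after shifts (permutation p = 0.002). By nearest start ncRNA genes did not pass, with 97 peaks against a mean of 86.1 (permutation p = 0.22). The values for miRNA, lincRNA, antisense RNA and rRNA genes did not pass the test across genes. For miRNA genes the summits did differ from shifts, with 1.80% in their windows against 0.284% (permutation p = 0.002, the smallest possible). Each replicate alone gave similar shares, 25% ± 0.462 for tRNA genes and 16% ± 0.613 for snoRNA genes (SD, n = 2, from the 501 strongest intervals of each). Genes that share a window share a peak, so the genes are not independent of each other.

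**Figure D2:**
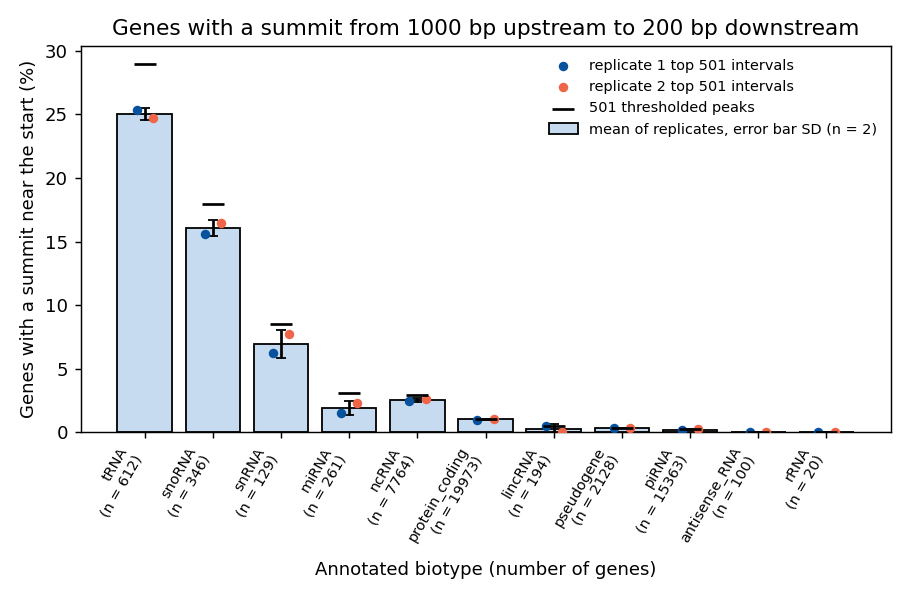
Share of genes of each annotated biotype (x axis) with a summit from 1000 bp upstream to 200 bp downstream of the start (y axis, percent). Bars give the mean of the 2 replicates with the SD, dots each replicate and dashes the thresholded peaks; tRNA genes (28.9%) and snoRNA genes (17.9%) stand above protein-coding genes (1.05%) in the thresholded list.

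Counted by peaks, 150 of the 501 summits (29.9%) lay within 250 bp of a tRNA gene start, against a mean of 0.308% after circular shifts, and 58 (11.6%) lay within 250 bp of a snoRNA gene start, against 0.171% (permutation p = 0.002 for each, two-sided, the smallest that 1000 shifts can give). The snoRNA peaks were concentrated at the top, with 10 of the 20 strongest peaks and 20 of the 50 strongest, while none of the 20 strongest lay at a tRNA gene. The reach of 250 bp was chosen after the data were seen. Where a tRNA gene was nearest, the median summit lay 17 bp inside the gene and 94.8% of 116 summits lay within 100 bp of the start. Where a snoRNA gene was nearest, the median summit lay 26 bp upstream of the start, and 83.6% of 55 lay within 100 bp. For the 194 peaks nearest to a protein-coding start, 19.1% lay within 100 bp.

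**Figure D3:**
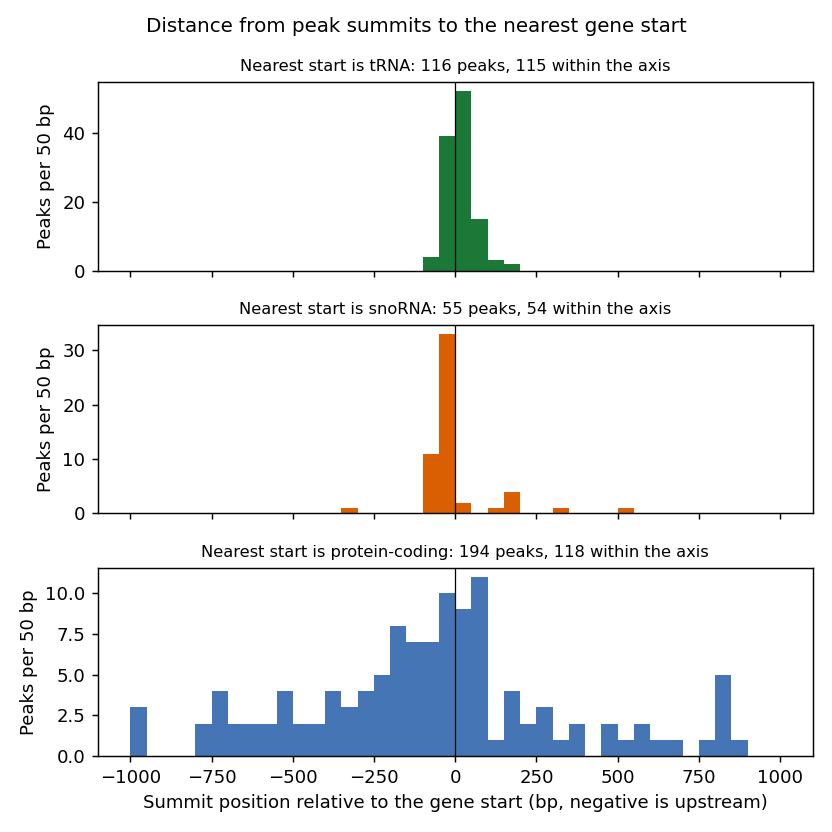
Number of thresholded peaks per 50 bp (y axis) by the position of the summit relative to the nearest gene start (x axis, bp, negative upstream), for peaks nearest to tRNA, snoRNA and protein-coding genes. Summits crowd at the starts of tRNA genes (94.8% within 100 bp) and just upstream of snoRNA genes (83.6%), and spread widely around protein-coding starts (19.1%).

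In relation to any annotated gene, 370 of the 501 summits (73.9%) lay from 1000 bp upstream to 200 bp downstream of a start, against 33.6% after circular shifts (permutation p = 0.002, two-sided, the smallest possible). Without the peaks at small RNA genes the share was 47.1% against 33.4% (permutation p = 0.002). Much of the excess thus lay at those genes, but a fall was built in, since the peaks were left out for lying near a start. Promoter windows of protein-coding genes held 176 summits (35.1%, 21.1% after shifts, adjusted permutation p = 0.0060). Coding exons held fewer than after shifts, 9.78% against 19.8% (adjusted permutation p = 0.0060), and so did introns, 25.1% against 30.9% (adjusted permutation p = 0.012). Coding exons held 14.2 and 12.6% of the strongest intervals of replicates 1 and 2, and without the peaks at small RNA genes coding exons and introns each held 15.2%. Intergenic sequence, 5' UTRs and 3' UTRs did not pass the test.

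Of 32 gene lists fixed before the data were examined, ribosomal protein genes had peaks more often than other protein-coding genes. Chemoreceptor genes had them less often, a call that was lost under several alternatives (adjusted permutation p = 0.20 with bound labels rotated along gene order). A summit lay in the promoter window of 8 of 78 ribosomal protein genes (10.3%, odds ratio 11.2, adjusted p = 5.0e-05, Fisher's exact test, Benjamini-Hochberg over the lists), against 1.05% of all protein-coding genes. The share was 8.97% in replicate 1 and 11.5% in replicate 2. Beside rpl-3, the members with the strongest peaks were rpl-15 (signal 230), rpl-35 (228) and rps-16 (184), all structural proteins of the ribosome, with summits 350 bp upstream, 451 bp upstream and 38 bp downstream of their starts. For the other members, rpl-18A, rps-3A, rps-19 and rps-20, the start nearest to the summit belonged to another gene (Y17G9B.5, F56F3.11, hsr-9 and ekl-4). The call held when bound labels were rotated along gene order (adjusted permutation p = 0.0064), and 7 of the 8 stayed when peaks at small RNA genes were left out, an alternative chosen after seeing the data. No other precipitation and no control library was analysed here. Peaks at these genes could thus not be told apart from sites recovered whatever protein is tagged.

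Chemoreceptor genes, the large families of putative odorant receptors, had 3 bound members of 1368 (0.219%, odds ratio 0.196, adjusted p = 0.0076, Fisher's exact test). Beside the rotation, the call was lost with the 250 strongest peaks (odds ratio 0.373, adjusted exact p = 0.90), with the window of 500 bp upstream to 100 bp downstream (adjusted exact p = 0.14) and without peaks at small RNA genes (adjusted exact p = 0.054). The 3 members were sre-23, srh-2 and srh-269. The start nearest to the summit belonged to another gene in each case, the snoRNA gene ZK265.10 for sre-23, the isocitrate lyase and malate synthase gene icl-1 for srh-2 and the tRNA gene T03E6.t1 for srh-269.

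Among nuclear hormone receptor genes, the family of the tagged protein, 1 of 274 was bound (0.365%, odds ratio 0.343, adjusted p = 1, Fisher's exact test). The share was 0.730% in each replicate alone, with odds ratios of 0.743 in replicate 1 and 0.682 in replicate 2. That member was nhr-255, with a summit 530 bp upstream of its start and 30 bp inside the tRNA gene ZK678.t1. Respiratory chain genes had 3 bound members of 43 (cox-6A, cox-5B and cox-5A; odds ratio 7.18, adjusted exact p = 0.11), the last through the peak that was weak in replicate 1, and translation factors 2 of 40 (odds ratio 5.02, adjusted p = 0.52), with 5% of genes in replicate 1 and 0% in replicate 2. Collagens and xenobiotic enzymes had 2 bound members each. Heat shock proteins, proteasome subunits, splicing factors, cell cycle genes, C-type lectins and F-box genes had 1 each, and none of these lists passed the test.

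No member was bound in the lists of tissue markers for pharynx (18 genes), body wall muscle (28), neurons (41), neuropeptides (147), intestine (29), epidermis and seam (16), somatic gonad (17), germ line (33) and sperm (54). With 1.05% of protein-coding genes bound, lists of this size have few bound genes by chance, and no test on them passed the threshold. The lists of homeobox, bHLH, forkhead, GATA factor and T-box genes, histones, vulva genes, heterochronic and molting genes, and Wnt and Notch or insulin and TGF-beta signalling also had no bound member. Among the strongest intervals of single replicates, 2.04% of neuropeptide genes were bound in replicate 1 and 2.78% of histone genes in replicate 2, and 0% in the other replicate.

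**Figure D4:**
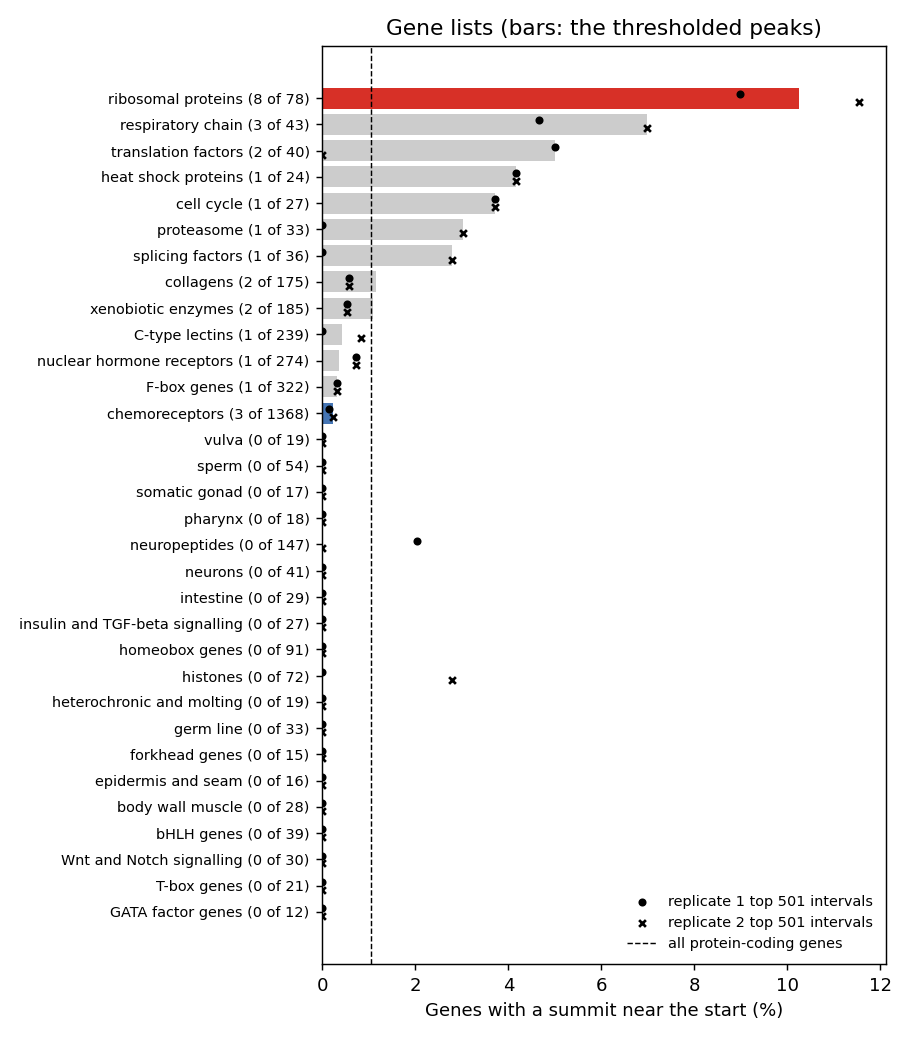
Share of genes with a summit from 1000 bp upstream to 200 bp downstream of the start (x axis, percent) for each of the 32 gene lists (y axis, with bound and total genes). Bars show the thresholded peaks, red where higher and blue where lower at adjusted p under 0.05 and grey otherwise, points and crosses the replicates, and the dashed line all protein-coding genes (1.05%); ribosomal proteins reach 10.3%.

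Peaks were spread over the 6 nuclear chromosomes unevenly. Chromosome III held 89 peaks (17.8%, against 13.7% of the genome length, adjusted p = 0.034, lost with the 250 strongest peaks at 18.4%, adjusted p = 0.083) and chromosome V 72 peaks (14.4%, against 20.9%, adjusted p = 0.0013, exact binomial tests, Benjamini-Hochberg over 6 chromosomes). Chromosome X held the most, 108 (21.6%, exact 95% interval 18 to 25.4%, against 17.7% of length), which did not pass the threshold (adjusted p = 0.052). It also held 276 of the 612 tRNA genes (45.1%) and 72 of the 150 peaks at tRNA genes (48.0%). When the peaks at tRNA genes were left out, an alternative chosen after seeing the data, 36 of 351 peaks lay on X (10.3%, exact 95% interval 7.29 to 13.9%), below its share of length (adjusted p = 0.00088). On the same peaks the call for chromosome V was lost (16.2%, adjusted exact p = 0.053), and chromosomes II and III each held 20.8%, above their shares of length (adjusted exact p = 0.012 and 0.0010). Over the autosomes, 54.2% of 393 peaks lay in the central part between 25 and 75% of chromosome length (exact binomial p = 0.11 against its share of length). Of autosomal protein-coding genes, 55.7% lay there.

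**Figure D5:**
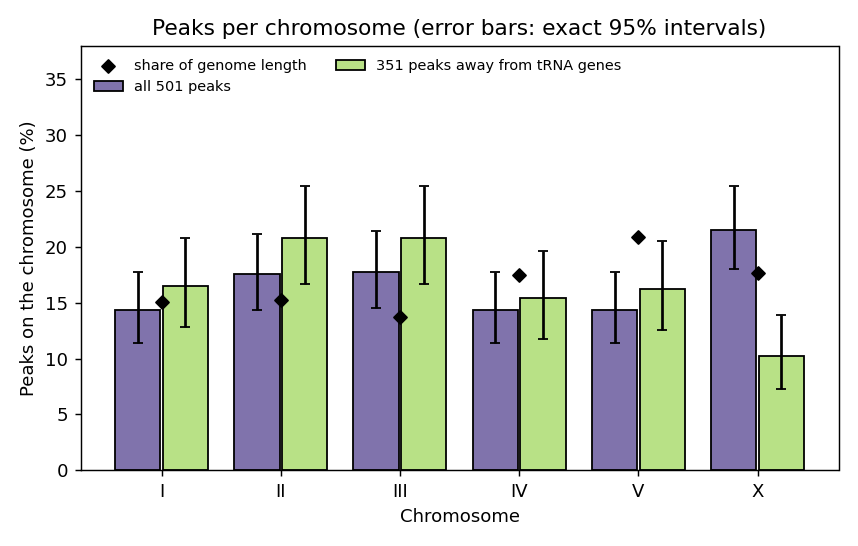
Percent of peaks on each chromosome (y axis) for all thresholded peaks and for the peaks away from tRNA genes, with exact 95% intervals, and the share of genome length as diamonds. On X the share is 21.6% for all peaks and 10.3% without the peaks at tRNA genes, on either side of its 17.7% of length.

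The sequence at the summits was richer in G and C than its surroundings. The mean GC content within 50 bp of the summit was 48.0%, and that of windows centred 300 bp away was 36.2%, a difference of 11.8 percentage points (permutation p = 1e-04, the smallest that 10000 sign flips can give). Of 2080 words of 6 bases, counted with their complements, 222 occurred in more summit windows than flank windows and 158 in fewer (exact sign test, Benjamini-Hochberg). The sign test does not correct for the difference in GC content. It also counts peaks as independent, although many lie at tRNA genes, most of which hold sequence that recurs in the genome. The leading words higher at summits were GAACCC, in 63 summit and 4 flank windows (adjusted exact p = 1.7e-12), CGAACC, in 66 and 7, and GTTCGA, in 86 and 18. These words match parts of the B box, the internal promoter element of tRNA genes. Without the peaks at tRNA genes, 65 words were higher and 69 lower. Among the higher were CGCGCA, in 41 summit and 5 flank windows (adjusted exact p = 8.9e-06), and CTGCGC, in 34 and 3 (adjusted exact p = 3.9e-05). Without the peaks at small RNA genes 1 word was higher and 17 lower. The higher word was CGCGCA (26 summit and 4 flank windows, adjusted exact p = 0.0057), while CTGCGC no longer passed (17 and 2, adjusted exact p = 0.071).

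Of the words fixed in advance, AGGTCA, the half-site of many nuclear receptors, occurred in 18 summit windows and 16 flank windows (adjusted p = 1, exact sign test). GAGAGA, CACGTG, GTGTCA and CCCCCC did not differ either (adjusted exact p = 0.63, 0.98, 0.94 and 0.20). The GATA word TGATAA occurred in 17 summit and 49 flank windows (adjusted exact p = 0.0013), and AAAAAA in 99 and 190 (adjusted exact p = 1.1e-07). Both were less frequent at summits. The higher GC content of summits by itself makes words rich in A and T rarer there, so these calls do not show that a motif is avoided. Without the peaks at tRNA genes the call for TGATAA was lost (10 and 26 windows, adjusted exact p = 0.11), while that for AAAAAA held (53 and 130, adjusted exact p = 2.3e-08).

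The transgene adds copies of nhr-111 and unc-119 to the genome, so the native loci were listed without a test. Within 20 kb of nhr-111 (chromosome V 16122895 to 16124839) lay 1 thresholded peak, the weakest of the 501, with its summit at 16136814, or −11975 bp from the nhr-111 start. It ranked 1021 in replicate 1 and 347 in replicate 2. Just short of the thresholded list, at pooled rank 503 with a signal of 101.4, an interval had its summit inside nhr-111, 1860 bp downstream of the start. The intervals at this site ranked 848 in replicate 1 and 500 in replicate 2. Among the 2500 strongest intervals of each replicate, 6 lay in this window in replicate 1 and 6 in replicate 2. Within 20 kb of unc-119 (chromosome III 10902641 to 10908935), a gene needed for nervous system function, there was no thresholded peak, and the 2500 strongest intervals included 0 in replicate 1 and 1 in replicate 2.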

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

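The analyses without peaks at tRNA or small RNA genes were chosen after seeing the data; the others were planned. Over the main comparisons, 41 combinations of a result and an alternative kept their direction and stayed on their side of the threshold or within a 1.5-fold range of the count, and 7 did not. A count does not say which lists, biotypes, chromosomes or words passed, and members changed under stable counts: with the 250 strongest peaks 2 lists passed without chemoreceptors (adjusted exact p = 0.90) and chromosome III lost its call (18.4%), and without peaks at tRNA genes X reversed, V was lost and II was gained. The share of shared intervals ran from 34.9 to 55.6%, rho from 0.30 to 0.37, and the share of summits near a start from 47.1 to 84.0% (68.1 to 70.7% with either replicate alone). Counts of lists past the threshold fell from 2 to 1 under 3 alternatives. These were the window of 500 bp upstream to 100 bp downstream, rotated bound labels, and leaving out peaks at small RNA genes. Ribosomal proteins were the list past the threshold in all 3, and the cause was not tested. With the window of 2000 bp upstream to 500 bp downstream the count rose to 3, so a list outside the main 2 passed there. Counts of words past the threshold were 380 in the main comparison and 135 with the 250 strongest peaks. They were 134 without peaks at tRNA genes and 18 without peaks at small RNA genes. Fewer peaks entered each of these, which lowers such counts. Peak number alone does not account for the fall to 18, which came from 244 peaks, against 135 words from 250 peaks. With the 250 strongest peaks, 0 peaks lay near nhr-111, since the 1 peak there is the weakest. The share of peaks on chromosome X lay above its share of length with all peaks, and below it, at 10.3%, without peaks at tRNA genes and, at 10.2%, without peaks at small RNA genes. For single lists, biotypes and chromosomes, 125 combinations were unchanged in direction and call, 8 became stronger, 6 weaker and 2 reversed, both on X. Chemoreceptors also lost their call with the 500 to 100 bp window and without peaks at small RNA genes, and V without peaks at small RNA genes (16.8%); miRNA genes gained one with both other windows (odds ratios 2.53 and 2.19). The higher share on X passed the threshold with the 250 strongest peaks (25.2%), with overlapping peaks merged (21.8%) and against the share of protein-coding genes. The autosome centre share passed with the 250 strongest peaks (59.4%) and with replicate 1 alone (55.6%). That test was against length, and 55.7% of autosomal protein-coding genes also lay in the centre. Overlap and correlation between replicates need both replicates, so neither could be left out there. Depth is unknown, so no limit from depth can be given for an interval listed in a single replicate.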

Other observations

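Apart from the comparisons of GC content and of tRNA genes on X with those on autosomes, the tests in this part were chosen only after the results they measure were seen. Intact tRNA genes carried summits much more often than tRNA pseudogenes. A summit lay within 250 bp of the start of 165 of 612 tRNA genes (27%) and of 5 of 209 tRNA pseudogenes (2.39%, odds ratio 15.1, p = 5.8e-18, Fisher's exact test). All 20 isotypes with at least 10 genes had at least 1 gene with a summit. Alanine tRNA genes stood highest, with 18 of 34 (52.9%, adjusted exact p = 0.021 over the 20 isotypes), and glycine tRNA genes among the lowest, with 8 of 55 (14.5%, adjusted exact p = 0.25). SL2 RNA genes, which encode the leader spliced to downstream genes of operons, had summits in 6 of 18 cases, against 7 (6.31%) of the other snRNA genes (odds ratio 7.43, p = 0.0030, Fisher's exact test). Among the other snRNA genes with summits were sup-6 and sup-39. snRNA genes with the ACAGAGA box of U6 did not differ from the rest, at 2 of 22 against 11 of 107 (p = 1, Fisher's exact test). A peak also lay at mrpr-1, the RNA of RNase MRP, with its summit 9 bp inside the gene and a mean signal of 77.1 ± 30.3 (SD, n = 2). snoRNA genes inside protein-coding genes had summits in 30 of 216 cases and those outside in 28 of 130 (odds ratio 0.588, p = 0.075, Fisher's exact test).

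The intervals that only a single replicate ranked highly differed from the others in 5 of 10 comparisons of position. In replicate 1, 25.9% of the 108 strong intervals without a match lay in coding exons, against 10.9% of the 393 with a match (adjusted p = 0.00085, Fisher's exact test over 10 comparisons). In replicate 2 the shares were 20.2 and 10.5% (adjusted exact p = 0.023). The reverse held at starts of small and other non-coding RNA genes, with 18.5% against 50.4% in replicate 1 (adjusted exact p = 8.3e-09) and 14.7% against 54.1% in replicate 2 (adjusted exact p = 3.1e-13). Intergenic shares passed the test in replicate 1 alone (14.8% against 25.7%, adjusted exact p = 0.041), and promoter windows and introns passed in neither. Of the 244 thresholded peaks away from small RNA genes, 103 (42.2%) lay in promoter windows of protein-coding genes and 37 (15.2%) in coding exons.

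High GC content alone does not account for the first pattern weighed, the concentration of summits at tRNA and snoRNA genes, since windows of the same GC content away from small RNA genes had a summit within 250 bp in 0.256% of 19160 cases, against 23.3% of the 958 tRNA and snoRNA genes. The test of reads shared between near-identical copies was split by biotype after its joint result had been seen (17.2% of 297 genes without recurring words). Such reads do not account for the snoRNA part. Of the 281 snoRNA genes without any recurring 31-base word within 200 bp of their midpoint, 18.1% had a summit, against 10.8% of the 65 with one. For tRNA genes the same test had 16 genes without such a word, 0 of which had a summit (an exact upper limit of 20.6%). Of the 596 tRNA genes with such a word, 165 had a summit (27.7%, exact 95% interval 24.1 to 31.5%). All tRNA genes with a summit within 250 bp thus held recurring sequence, and shared reads stay open there. Binding at the half-site AGGTCA does not account for most of these peaks, as 15.4% of the 208 at tRNA or snoRNA genes held it within 200 bp of the summit (exact 95% interval 10.8 to 21%; flanks 11.5%), while other words stay open because the one NHR-111 recognises is not given in the sources used here. Sites recovered whatever protein is tagged are a further candidate explanation that no table decides, because no other precipitation and no control library was analysed here.

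The second pattern is the share of peaks on chromosome X. A higher dosage of X in the animals would raise its other peaks too. Without peaks at tRNA genes X held 10.3% of peaks (exact interval 7.29 to 13.9%), against 17.7% of length and 13.7% of protein-coding genes. These other peaks lay below the share of length of X (adjusted p = 0.00088, exact binomial test). This argues against a higher dosage of X as the source, although their share without a dosage effect is not known. The share of 10.3% goes with the number of tRNA genes on X as the source of the higher share, a hypothesis found and tested on the same peaks. A fall was built in, since 48.0% of the peaks left out lay on X. Whether each tRNA gene on X also carries summits more often cannot be told apart from chance, as 29.7% of those on X and 24.7% of those on autosomes had a summit (odds ratio 1.29, p = 0.17, Fisher's exact test).

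The third pattern is the number of strong intervals around native nhr-111. Among the 501 strongest intervals, 2 lay within 20 kb in replicate 1 and 3 in replicate 2, as many as in 3.21 and 0.620% of 10000 random windows of the same length. The pooled list had 1, as many as in 17.2%. Among its 1000, 2500 and 5000 strongest intervals there were 4, 5 and 7, as many as in 0.72, 2.27 and 3.3%. The other list depths were added after values at earlier depths had been seen. Chance placement stays open, since the highest such share over the replicate lists and depths from 501 to 5000 was 5.73%, and over the full lists it was 16 and 76%. Extra copies of the transgene region are a candidate explanation that could not be decided, as 0 of the 5000 strongest intervals lay near unc-119 in replicate 1 and 1 in replicate 2 (at least as many in 81.5% of random windows for replicate 2), and the extent of the unc-119 fragment is not given in the sources used here. Regulation of nhr-111 by its own product was not tested.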
